A study of Homo sapiens with 6 samples.

How the data were processed

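Poly(A) RNA of HEC-1A cells was sequenced in 6 libraries, 3 labelled control and 3 labelled C1orf106 knockdown. Libraries were assigned to groups by the treatment label and named by the replicate number in their titles. The series description speaks of duplicates, while the labels list 3 libraries per group. All 6 were used.

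The authors deposited 1 table of FPKM values (fragments scaled by gene length and by a library total), with 1 column per library and 58735 gene rows, and with gene lengths, biotypes and coordinates. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without roles, and the build GRCh38. The strand setting of the counting and the definition of the library total are not given in the sources used here. All 58735 gene IDs, with their start, end and strand, matched GENCODE v29, which was used for transcript length and for exon overlap.

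FPKM multiplied by gene length was a whole multiple of 1 step in each library for 100% of values (within 0.01 read), so reads per gene were recovered. They summed to 1.47e+07 to 1.66e+07 per library. In all 6 libraries the total implied by the FPKM scaling was in the same ratio to the median-of-ratios size factor of the recovered reads, so the deposited FPKM values were already on a median-of-ratios scale up to a constant factor. Values scaled this way assume that most genes do not differ, and a change in total RNA per cell would not show. FPKM also carries any difference between libraries in how evenly long and short transcripts were sampled.

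The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), over 13070 genes with a mean of at least 1 FPKM in the 6 libraries, with Benjamini-Hochberg adjusted p under 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors of fold changes are standard errors from limma, and errors of FPKM values are SDs over 3 libraries. The target gene was also tested with an exact two-sided permutation test. With 40 gene lists fixed before the data were examined, limma camera was run with a preset inter-gene correlation of 0.01 on the 37 lists with at least 3 tested members, adjusted over the lists. For each list, members past the test over all genes and members past it adjusted over the list alone were counted.

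Genes were named by a rule fixed before the data were examined. It took INAVA, then the 12 largest rises and the 12 largest falls among protein-coding genes past the test whose groups did not overlap and whose higher mean was at least 2 FPKM, and up to 4 members with the smallest adjusted p of each list discussed. Genes named outside this rule are said to be so. Results for 3 of the genes the rule picks, and for 1 gene list, are not reported here. A gene whose groups do not overlap is expected by chance in 10% of genes with 3 against 3 libraries.

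Settings varied in turn were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, median-of-ratios rescaling, quantile normalization, TPM, no intensity trend, robust eBayes, voom on the recovered reads, array weights, a replicate block, protein-coding genes only, a 2-fold minimum, each library left out in turn, camera with an estimated correlation, and fry. After the data were examined, 4 more were added: removal of a loess trend on transcript length (span 0.3) from each library, and a 2-fold minimum, camera with an estimated correlation and voom, each without control library 1. No group had enough libraries for an outlier test.

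The procedure was tested on simulated data with 200 changed genes. With 6 like libraries it recovered 93% of 2-fold and 100% of 4-fold changes with 12 false calls among 12908 genes. With the profile of control library 1 kept as measured it recovered 20% of 2-fold and 81% of 4-fold changes with 0 false calls among 12886 genes.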

Results

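RNA was sequenced from HEC-1A cells, an established human endometrial adenocarcinoma line, in 3 control libraries and 3 libraries labelled as C1orf106 knockdown. C1orf106, now named INAVA, encodes an adaptor protein of epithelial cells with known roles at adherens junctions and in innate immune signalling. The comparison asks which transcripts differed between cells with reduced C1orf106 and control cells. The labels give neither the RNAi reagent nor whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads recovered from the deposited FPKM values (length-scaled fragment counts) came to 1.47e+07, 1.56e+07 and 1.66e+07 in control libraries 1, 2 and 3, and to 1.66e+07, 1.66e+07 and 1.63e+07 in knockdown libraries 1, 2 and 3.

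The targeted gene was lower in every knockdown library than in every control library. INAVA (ENSG00000163362) is a protein-coding gene on the plus strand of chromosome 1, from 200891048 to 200915735 in GRCh38. It measured 20.4, 14.9 and 16.4 FPKM in control libraries 1, 2 and 3, and 6.81, 7.45 and 6.90 FPKM in knockdown libraries 1, 2 and 3. The mean was 17.2 ± 2.80 FPKM in control (SD, n = 3) and 7.05 ± 0.346 FPKM in knockdown (SD, n = 3), which is 40.9% of control. The log2 fold change was -1.17 ± 0.14 (SE, limma adjusted p = 0.0135). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The limma adjusted p was 0.0536 without control library 3, and 0.118, 0.108 and 0.102 without knockdown library 1, 2 or 3. It ran from 4.52e-06 to 0.118 over 21 alternative settings, with log2 fold changes of -1.46 to -0.88.

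**Figure D1:**
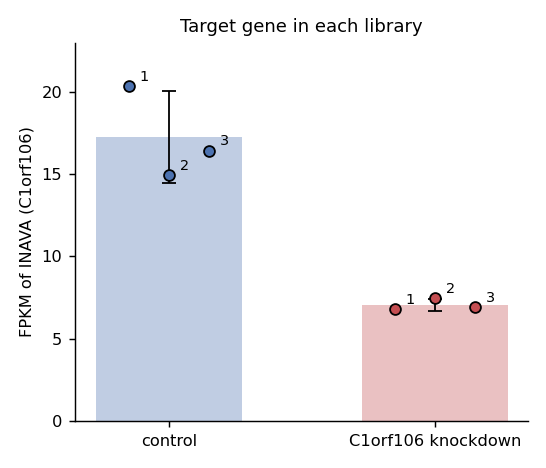
FPKM of INAVA (C1orf106) in each library: points are libraries with their replicate number, bars are group means and error bars are the SD (n = 3). The knockdown libraries lie between 6.81 and 7.45 FPKM, below all control libraries, which lie between 14.9 and 20.4 FPKM.

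Control library 1 stood apart from the other 5 libraries. Across tested genes, which are not independent replicates, its log2 values had a Pearson correlation of 0.852 and 0.864 with control libraries 2 and 3. The corresponding value was 0.982 between control libraries 2 and 3, and 0.986 to 0.989 among the knockdown libraries. Genes with short transcripts read low in control library 1 and genes with long transcripts read high. Against the mean of control libraries 2 and 3, the median log2 difference was -1.18 over 896 protein-coding genes with transcripts under 1000 bases, and 0.62 over 1563 genes with transcripts over 5000 bases. The same medians for the knockdown mean against control libraries 2 and 3 were 0.06 and -0.01. Counts of genes past the test are therefore given with all 6 libraries and, beside them, with control library 1 left out.

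**Figure D2:**
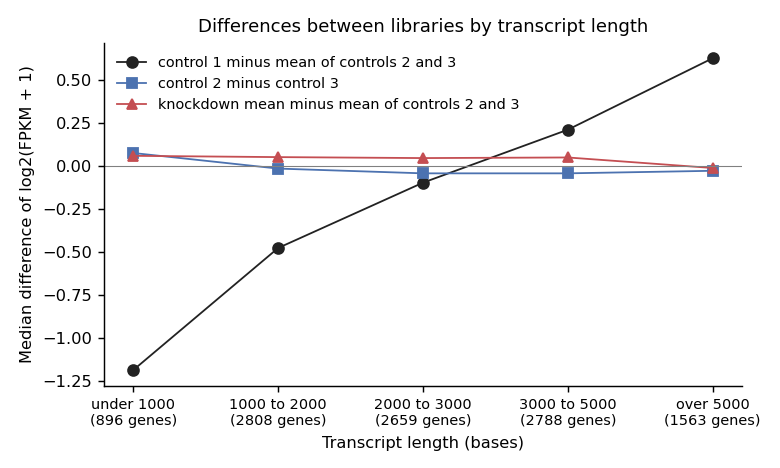
Median difference of log2(FPKM + 1) for protein-coding genes in 5 classes of transcript length in bases, with the number of genes in each class. The line for control 1 against controls 2 and 3 climbs from -1.18 to 0.62, while control 2 against control 3 and the knockdown mean against controls 2 and 3 stay between -0.04 and 0.07.

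In the knockdown libraries, 14 of 23 tested genes of the amino acid and integrated stress response list fell and 0 rose, and of 18 YAP/TAZ target genes 6 fell and 1 rose. Both lists were lower by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.369 for each). Of 18 glycolysis, 15 heat shock and 28 interferon response genes 4, 2 and 5 rose and 0 fell. Of 13070 genes tested, 442 were higher and 317 lower in the knockdown, 759 in all (limma, adjusted p under 0.05). At a minimum of 2-fold, 87 were higher and 135 lower. These 2-fold counts depended on the setting, with 22 higher and 48 lower at a pseudocount of 5. At a pseudocount of 0.1 they were 153 and 184, and with voom 183 and 193. None of the 759 genes changed sign in any alternative setting in which it was tested. Settings that alter only the filter, the variance estimate or the block leave fold changes as they were, so no sign could change there. The genes were also selected in these same libraries. Converted to TPM, 136 genes were higher and 338 lower, and the median log2 fold change of all tested genes moved from 0.05 to -0.14. Without control library 1, 4657 of 12936 tested genes passed, 2678 higher and 1979 lower. They included all 748 of the 759 genes that were tested there. Counts of list members without that library are to be read against this share of all genes. Without control library 2 or 3, 145 and 103 genes passed, and without knockdown library 1, 2 or 3, 5, 2 and 2 passed.

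The 12 largest falls included 4 amino acid transporter genes, SLC7A11, SLC7A5, SLC3A2 and SLC1A4. The largest was in GDF15. This gene, a stress-induced cytokine (chromosome 19, 18374731 to 18389176), fell from 48.5 ± 29.01 to 2.19 ± 0.310 FPKM (SD, n = 3 per group). Its log2 fold change was -3.74 ± 0.49 (SE, adjusted p = 0.0184), and its control values were 18.4, 50.7 and 76.3 FPKM. SLC7A11, the cystine and glutamate exchanger (chromosome 4, 138164097 to 138242349), fell from 17.8 ± 6.70 to 1.02 ± 0.145 FPKM, a log2 fold change of -3.16 ± 0.24 (adjusted p = 0.00623). SLC7A5 and SLC3A2 encode the chains of one large neutral amino acid transporter. SLC7A5 fell from 126 ± 26.6 to 19.3 ± 1.25 FPKM (log2 fold change -2.62 ± 0.19) and SLC3A2 from 54.5 ± 17.3 to 11.8 ± 1.13 FPKM (-2.07 ± 0.26). SLC1A4, a neutral amino acid transporter, fell by 2.05 on the log2 scale, from 10.4 ± 1.71 to 1.75 ± 0.144 FPKM. The surface glycoprotein CD24 fell from 13.9 ± 1.10 to 1.43 ± 0.0930 FPKM and the arylsulfatase ARSE from 7.90 ± 0.196 to 0.797 ± 0.0546 FPKM, both with an adjusted p of 0.00112. The value of CD24 is uncertain, because close copies of the gene lie elsewhere in the genome. CHAC1, a glutathione-degrading enzyme, had a log2 fold change of -2.26, the secreted glycoprotein STC2 -2.24, the transcription factor ATF5 -2.20, the peptide hormone gene ADM2 -2.18 and the membrane protein TM4SF4 -2.03. Of the exon bases of ATF5, 23.7% overlap IL4I1, MIR4751 or NUP62, so reads of these genes may not be told apart.

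Among the 12 largest rises, SERPINB5, the serpin maspin (chromosome 18, 63476761 to 63505085), rose from 0.934 ± 0.101 to 7.28 ± 0.175 FPKM (SD, n = 3 per group), a log2 fold change of 2.10 ± 0.09 (adjusted p = 0.00176). ENO2, the neuronal enolase (chromosome 12, 6913745 to 6923698), rose from 9.74 ± 3.04 to 45.7 ± 1.17 FPKM, a log2 fold change of 2.16 ± 0.22 (adjusted p = 0.0105). NDRG1, a hypoxia-responsive gene, rose from 60.7 ± 9.59 to 204 ± 5.23 FPKM, a log2 fold change of 1.74 ± 0.17. TUBA4A, an alpha-tubulin, rose from 9.09 ± 0.278 to 29.01 ± 1.93 FPKM, and DEPP1, a FOXO target, from 3.44 ± 0.0703 to 11.8 ± 0.113 FPKM. CTXN1 had a log2 fold change of 2.29, TMEM158 1.98, the metallothionein MT1X 1.70, the neuroserpin gene SERPINI1 1.64, the interferon-induced IFI44 1.63, the syntaxin STX1A 1.62 and the aldolase ALDOC 1.59. Exons of other annotated genes overlap 23.3% of the exon bases of DEPP1, 18.1% of TUBA4A, 18.1% of MT1X, 17.9% of STX1A, 10.1% of ALDOC and 9.89% of CTXN1, and MT1X and TUBA4A have close paralogs, so these values are uncertain. All 24 of these genes passed without control library 1. Without control library 2 or 3, 14 and 12 passed, and without knockdown library 1, 2 or 3, 3, 2 and 2 passed. Several rises were smaller without control library 1. Their log2 fold changes there were 1.22 for ALDOC, 1.34 for STX1A, 1.36 for MT1X, 1.38 for IFI44 and 1.41 for SERPINI1. ENO2 (1.93), CTXN1 (2.08), SERPINB5 (2.08) and TUBA4A (1.56) were also smaller there. TMEM158 (2.04), NDRG1 (1.75) and DEPP1 (1.54) were not.

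Of the 23 tested members of the amino acid and integrated stress response list, which was fixed before the data were examined, 14 fell, 0 rose and 9 did not pass, with 20 lower when adjusted over the list alone. The median log2 fold change was -1.39 and the camera adjusted p was 1.45e-15, or adjusted p = 0.369 with an estimated correlation. Besides SLC7A5 and SLC7A11, the members with the smallest adjusted p were AARS, the alanyl-tRNA synthetase, and CEBPG, a transcription factor. AARS fell from 92.0 ± 6.45 to 31.7 ± 0.320 FPKM, a log2 fold change of -1.51 ± 0.12, and CEBPG from 30.0 ± 1.38 to 12.9 ± 0.184 FPKM, a log2 fold change of -1.16 ± 0.10. ATF4, the transcription factor at the centre of this response, is named after its values were seen. It fell from 178 ± 52.8 to 43.5 ± 3.52 FPKM, a log2 fold change of -1.96 ± 0.26 (adjusted p = 0.0184). DDIT3, also named after its values were seen, did not pass (-1.48 ± 0.55, adjusted p = 0.156). It measured 13.04 ± 8.12 FPKM in control and 3.22 ± 0.190 in knockdown. With control library 1 left out, 21 members fell, 1 rose and the list median was -1.57.

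**Figure D3:**
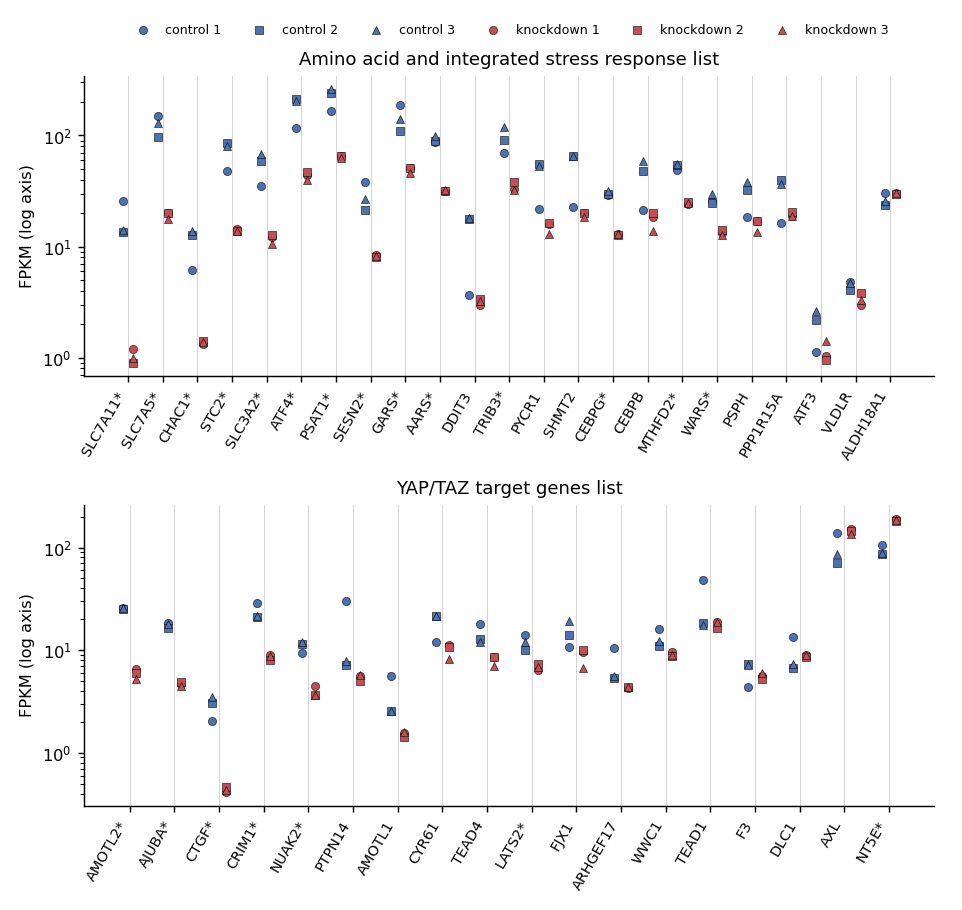
FPKM on a log axis of every tested member of the amino acid and integrated stress response list (top) and of the YAP/TAZ target list (bottom), ordered by log2 fold change. Each point is 1 library (blue control, red knockdown, marker shape for the replicate number) and an asterisk marks a limma adjusted p under 0.05, met by 14 of 23 members in the top panel and 7 of 18 in the bottom panel.

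YAP/TAZ target genes, which respond to the transcriptional co-activators of the Hippo pathway, included more falls than rises. Of 18 tested members 6 fell, 1 rose and 11 did not pass, and adjusted over the list alone 11 were lower and 1 higher. The median log2 fold change was -0.72 (camera adjusted p = 5.23e-06, adjusted p = 0.369 with an estimated correlation). AMOTL2, an angiomotin family member, fell from 25.5 ± 0.508 to 5.94 ± 0.653 FPKM (log2 fold change -1.94 ± 0.11) and the LIM protein gene AJUBA from 17.5 ± 1.07 to 4.69 ± 0.165 FPKM (-1.70 ± 0.10). The kinase gene NUAK2 had a log2 fold change of -1.28 ± 0.13 and CRIM1 of -1.36 ± 0.15. The member that rose was NT5E, an ectonucleotidase named after its values were seen, from 93.5 ± 10.9 to 185 ± 4.38 FPKM. With control library 1 left out, 14 members fell and 3 rose, while the list median was smaller at -0.54. The camera adjusted p was then 0.000238, or 0.545 with an estimated correlation.

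The glycolysis, heat shock and interferon response lists held members that rose. Of 18 glycolysis members 4 rose (6 adjusted over the list alone) and 0 fell, with a median log2 fold change of 0.60 (camera adjusted p = 0.000442, adjusted p = 0.544 with an estimated correlation). Those that rose were ENO2, ALDOC, HK1 (log2 fold change 0.82 ± 0.16) and GPI (0.73 ± 0.14). ALDOC was near the threshold (limma adjusted p = 0.0493). It did not pass, among other settings, at a pseudocount of 0.1 (0.0517), with quantile normalization (0.0553) or with robust eBayes (0.0542). It passed without control library 1 (0.00164). Of 15 heat shock members 2 rose, HSP90AA1 (1.03 ± 0.17, from 117 ± 16.7 to 237 ± 9.82 FPKM) and HSPA4L (0.66 ± 0.11). Adjusted over the list alone, 9 heat shock members were higher and 1 lower, and the median was 0.43 (camera adjusted p = 0.00249, adjusted p = 0.369 with an estimated correlation). HSP90AB1 (0.78 ± 0.18, adjusted p = 0.0588) and HSPH1 (0.43 ± 0.10, adjusted p = 0.0673) did not pass. Of 28 interferon response members 5 rose and 0 fell, and 8 were higher and 1 lower adjusted over the list alone. OASL rose from 3.77 ± 0.397 to 10.5 ± 0.371 FPKM (1.27 ± 0.10), and IFI44, HERC5 (0.89 ± 0.12) and IFIT2 (0.81 ± 0.14) rose too. The interferon list median was 0.26 (camera adjusted p = 0.0173, adjusted p = 0.369 with an estimated correlation). In the 5 libraries other than control library 1, 11 glycolysis, 12 heat shock and 13 of 27 tested interferon members rose, and 0, 1 and 2 fell. The list medians there were 0.42, 0.44 and 0.22.

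The estrogen response and steroid receptor list has 18 members, of which 9 were tested. Of these 3 fell, and 3 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0210, adjusted p = 0.369 with an estimated correlation). The members that fell were STC2, XBP1, a transcription factor also known from the unfolded protein response (-1.21 ± 0.13), and the scaffold gene PDZK1 (-1.39 ± 0.21). CA12 did not pass (-0.28 ± 0.12, adjusted p = 0.205). Without a filter the list median was -0.03 and the list did not pass camera (adjusted p = 0.0798). With 5 libraries, leaving out control library 1, 5 members of this list fell and 1 rose. Of 20 PI3K/AKT/mTOR and FOXO members AKT1 alone passed and rose (0.55 ± 0.10), also when adjusted over the list alone, although the list median was -0.38 and camera placed the list below other genes (adjusted p = 0.0130, adjusted p = 0.777 with an estimated correlation). AKT2 (-0.39 ± 0.10) and PIK3R3 (-0.37 ± 0.10) did not pass. Without control library 1, 8 members fell and 4 rose, and the camera adjusted p of this list was 0.0840, and it ran from 0.00159 to 0.186 over 21 settings.

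The lists of cytosolic ribosomal proteins and of nuclear-encoded respiratory chain subunits passed camera although 0 of 35 and 0 of 25 members passed the limma test, and 0 adjusted over either list alone. At an unadjusted p under 0.05 the limma test passed 3472 genes in all. The median log2 fold change was 0.67 for ribosomal proteins (camera adjusted p = 0.0470, adjusted p = 0.811 with an estimated correlation) and 0.41 for respiratory chain subunits (0.0275, adjusted p = 0.777 with an estimated correlation). Without control library 1, the medians were 0.08 and 0.09, and the camera adjusted p was 0.980 and 0.387. There 4 ribosomal protein genes rose and 5 fell, and 5 respiratory chain genes rose and 0 fell. The higher medians of these lists with all 6 libraries thus depended largely on control library 1. After removal of the length trend the medians were 0.49 and 0.24, and the camera adjusted p was 0.0555 for each. Over 21 settings the camera adjusted p of these lists ran from 0.000716 to 0.980 and from 0.000325 to 0.387. RPL26 measured 6.78 ± 3.89 FPKM in control and 12.95 ± 1.07 in knockdown, and UQCRC2 15.2 ± 1.71 and 20.4 ± 0.582 FPKM (adjusted p = 0.199 and 0.0986).

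**Figure D4:**
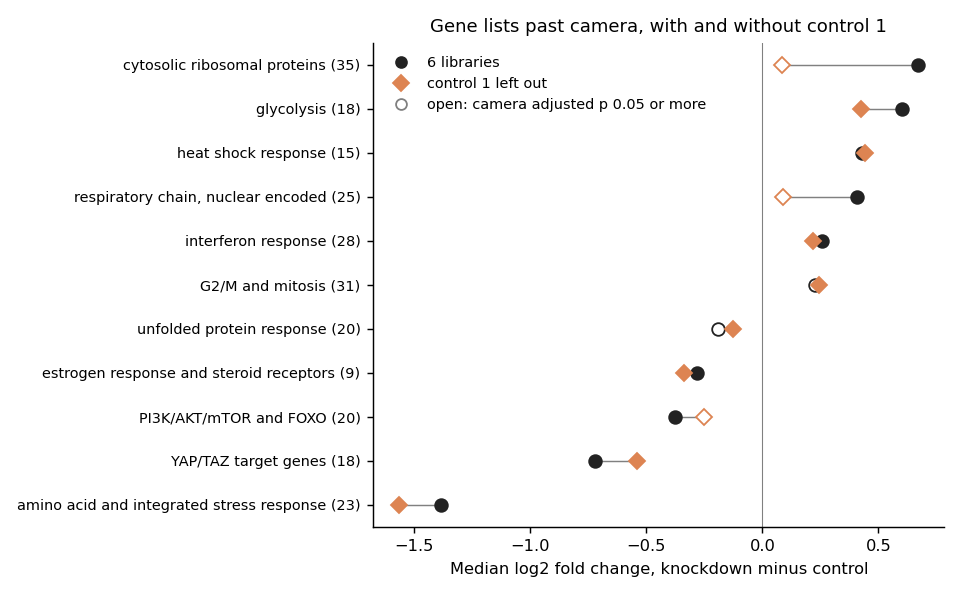
Median log2 fold change (knockdown minus control) of the gene lists past camera with all 6 libraries or with control library 1 left out, with the number of members tested in parentheses. Circles are 6 libraries, diamonds are 5, and open symbols are camera adjusted p of 0.05 or more; the ribosomal protein median moves from 0.67 to 0.08 and the stress response median from -1.39 to -1.57.

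Junction and epithelial genes, which relate to the known role of C1orf106, were mostly not past the test with all 6 libraries. None of 15 adherens junction and desmosome members passed limma, and 0 adjusted over the list alone. Leaving out control library 1, 7 rose and 0 fell. PKP2, a desmosomal plakophilin, had a log2 fold change of 0.42 ± 0.12 (adjusted p = 0.0983) and JUP, plakoglobin, of 0.61 ± 0.21 (adjusted p = 0.143). CDH1, E-cadherin, named after its values were seen, measured 59.8 ± 5.38 FPKM in control and 56.7 ± 0.547 in knockdown (adjusted p = 0.729). Of 17 tight junction members PARD6B, a polarity protein gene, fell from 12.7 ± 2.43 to 5.03 ± 0.668 FPKM (-1.17 ± 0.16, adjusted p = 0.0192), and 2 were lower and 2 higher adjusted over the list alone. The occludin gene OCLN had a log2 fold change of -0.41 ± 0.09 (adjusted p = 0.0563). Of 19 epithelial identity members the transcription factor ELF3 fell (-0.73 ± 0.12), and 1 adjusted over the list alone, while KRT7 did not pass (-0.63 ± 0.19, adjusted p = 0.104). None of 10 mesenchymal transition members passed, and 2 were higher and 1 lower adjusted over the list alone. Of 13 genes in the list of C1orf106 and its known partners, INAVA alone passed. The test without control library 1 gave 4 falls and 2 rises for tight junction, 6 and 0 for epithelial identity, 2 and 2 for mesenchymal transition and 2 and 3 for C1orf106 and its partners. PKP2 (0.52, limma adjusted p = 0.00269) and JUP (0.74, adjusted p = 0.0154) passed in that test. OCLN (-0.40, adjusted p = 0.00567) and KRT7 (-0.74, adjusted p = 0.00527) passed too, while CDH1 did not (adjusted p = 0.936). With all 6 libraries the camera adjusted p was 0.756 for adherens junction and desmosome, 0.189 for tight junction and 0.304 for epithelial identity. It was 0.445 for mesenchymal transition and 0.937 for C1orf106 and its partners. Without control library 1 these values were 0.0840, 0.387, 0.109, 0.626 and 0.951 in the same order. The adherens junction and desmosome median was 0.04 with all 6 libraries and 0.25 without control library 1.

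With all 6 libraries cell cycle and cell death lists did not pass camera. Of 31 G2/M members the kinetochore gene NUF2 rose (0.63 ± 0.12, adjusted p = 0.0421), 0 passed adjusted over the list alone, and the median was 0.23 (camera adjusted p = 0.0635). Without control library 1, 14 G2/M members rose, 1 fell and the camera adjusted p was 0.00356 (adjusted p = 0.405 with an estimated correlation), within a range of 0.000737 to 0.195 over 21 settings. Of 32 G1/S and replication members E2F2 fell (-0.78 ± 0.13, adjusted p = 0.0274), and 2 were higher and 4 lower adjusted over the list alone. Among cell cycle inhibitors and p53 targets SESN2 fell (-1.65 ± 0.22) and RRM2B, a ribonucleotide reductase subunit, rose (0.55 ± 0.10). The pro-apoptotic BCL2L11 fell (-0.64 ± 0.11) and the anti-apoptotic BIRC2 rose (0.62 ± 0.10), 1 member of each list of 17 and 10 tested. The counts without control library 1 were 9 rises and 11 falls for G1/S and 6 and 5 for inhibitors and p53 targets. They were 3 and 2 for pro-apoptotic and 4 and 3 for anti-apoptotic genes. Over all genes there, 2678 of 12936 rose and 1979 fell, so counts near these shares say little about a list.

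Of 21 hypoxia members 5 rose and 3 fell, with 8 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.199). NDRG1, MXI1 (0.80 ± 0.10) and ERO1A (0.96 ± 0.12) rose, while STC2 fell. VEGFA, named after its values were seen, fell from 12.6 ± 2.68 to 5.19 ± 0.240 FPKM. Of 24 cholesterol synthesis members 4 rose, among them MSMO1 (0.85 ± 0.13), IDI1 (0.71 ± 0.12) and INSIG1 (0.66 ± 0.12), and 9 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0704). The desaturase genes FADS2 (-0.87 ± 0.13) and SCD (-1.05 ± 0.21) fell and DGAT2 rose (0.51 ± 0.09) among 18 lipid synthesis members. Among TGF-beta targets ID1 rose from 47.2 ± 5.62 to 120 ± 19.8 FPKM (1.32 ± 0.18), while CTGF (-1.41 ± 0.17), COL4A1 (-0.64 ± 0.08) and SMAD6 (-0.65 ± 0.13) fell. The laminin chain gene LAMB3 rose (1.00 ± 0.17) and the collagen gene COL4A2 fell (-1.05 ± 0.11) in the matrix list. PHLDA1 rose (1.19 ± 0.09) and EGR1 fell (-1.50 ± 0.14) among immediate early genes. AKR1C2 (-0.99 ± 0.19) and SLC7A11 fell among NRF2 targets. Of 20 unfolded protein response members XBP1 alone passed, and 9 fell without control library 1, where the camera adjusted p was 0.0186 (adjusted p = 0.405 with an estimated correlation) against 0.126 with all libraries and 0.0148 to 0.275 over 21 settings. Leaving that library out gave 9 rises and 4 falls for hypoxia, 11 and 5 for cholesterol synthesis, 6 and 5 for lipid synthesis and 4 and 8 for TGF-beta targets. It gave 9 and 7 for matrix, 4 and 4 for immediate early and 6 and 6 for NRF2 target genes.

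In the remaining lists few members passed with all 6 libraries. IRAK2 rose (0.69 ± 0.13) among 20 NF-kB and inflammatory genes, TAP1 (0.71 ± 0.13) among 14 antigen presentation genes, NKD2 (0.93 ± 0.14) among 6 Wnt targets, JAG2 (0.82 ± 0.12) among 10 Notch genes and PRKRA (0.57 ± 0.09) among 13 small RNA machinery genes. WIPI1 rose (0.66 ± 0.11) and MCOLN1 fell (-0.48 ± 0.10) among 23 autophagy and lysosome genes. None of 27 MYC and ribosome biogenesis genes, 19 homologous recombination and mismatch repair genes or 13 mitochondrial genome transcripts passed limma. Leaving out control library 1 gave 1 rise and 6 falls, 3 and 2, and 4 and 0 for these 3 lists, and 9 rises and 5 falls for the NF-kB list. It gave 3 rises and 0 falls for antigen presentation, Wnt and Notch genes each, 3 and 2 for small RNA machinery and 3 and 8 for autophagy and lysosome genes. In 9 lists, 0 of them past camera, the median, the mean and the camera direction did not all have the same sign. Of 37 lists with at least 3 tested members 9 passed camera with a preset correlation of 0.01, and 0 passed with an estimated correlation.

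Markers of other cell types were low in all libraries. None of 15 leukocyte and none of 11 endothelial markers reached a mean of 1 FPKM over the 6 libraries. Of 13 fibroblast or stromal markers COL1A1 and TAGLN did, and neither passed limma, while 1 was higher adjusted over the list alone. Without control library 1, COL1A1 rose (adjusted p = 0.00475). The highest value of any fibroblast marker in any library was 3.13 FPKM, for COL1A1, which measured 1.62 ± 0.392 FPKM in control and 2.96 ± 0.204 in knockdown (adjusted p = 0.0614).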

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

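The removal of the length trend and the settings that join another change to leaving out control library 1 were chosen after the data were examined. The count of 759 genes (442 higher, 317 lower) stayed within 1.5 times with pseudocounts of 0.1 and 5, median-of-ratios rescaling, quantile normalization, no intensity trend, robust eBayes, voom and protein-coding genes only, with 635 to 973 genes. Median-of-ratios rescaling gave the same 759 genes, with 218 instead of 222 at 2-fold or more. The deposited values were already on that scale, so this setting applied the same factor to all libraries and is no independent check. The count at 2-fold or more was less stable, with 70 genes at a pseudocount of 5, 337 at 0.1 and 376 with voom. The count was 292 (141 higher, 151 lower) without a filter and 417 (247 higher, 170 lower), with 3 gene lists, at a mean of 5 FPKM, where fewer genes were tested. It was 474 as TPM, with 136 higher, and 222 (87 higher, 135 lower) with a 2-fold minimum, or 312 with that minimum and control library 1 left out. It was 5949 (3301 higher, 2648 lower) with array weights, 1767 (926 higher, 841 lower) with the length trend removed and 5340 (3041 higher, 2299 lower) with voom without control library 1. Leaving out 1 library at a time gave 2 to 4657 genes, 0 to 2678 higher and 2 to 1979 lower, and a log2 fold change of INAVA of -1.26 to -1.05. The highest count came without control library 1 and the lowest without a knockdown library. In the simulated data, keeping the profile of control library 1 lowered the recovery of 2-fold changes from 93% to 20%. Without knockdown library 1, 2 or 3 the fold changes had a correlation of 0.99 with those of the main test across genes. Without control library 1, 2 or 3 it was 0.84, 0.97 and 0.97. Each of these fits shares all its libraries with the main test, so a high correlation is no independent check. How much of the differences in count comes from the spread that control library 1 adds was not tested.

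With a replicate block limma called 0 genes (0 higher, 0 lower), against 2540 at an unadjusted p under 0.05, and INAVA had a log2 fold change of -1.17 with an adjusted p of 0.117. Deviations of same-numbered libraries from their group means had correlations of -0.03, 0.21 and -0.29 across genes. For replicates 1 and 3 another number correlated better, while for replicate 2 its own number did (0.21 against -0.003). The outlying profile of control library 1 enters the mean from which every control deviation was taken. These correlations therefore do not decide whether the replicate numbers mark pairs.

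Of the 9 lists past camera 0 passed with an estimated correlation, also 0 without control library 1, while voom gave 9, TPM 12 and fry 12. By fry the PI3K, ribosomal protein and respiratory chain lists did not pass (adjusted p = 0.249, 0.525 and 0.321), and 6 others did, G2/M (0.0125), Wnt (0.00196), mesenchymal transition (0.0175), cholesterol synthesis (0.0176), hypoxia (0.0428) and tight junction (0.0429). Stress response, YAP/TAZ and glycolysis lists passed camera with the preset correlation in all 21 other settings, heat shock and interferon in 20 and estrogen response in 18. Their camera adjusted p ran from 7.86e-21 to 7.30e-13, 5.95e-07 to 0.000238, 2.84e-06 to 0.0173, 4.86e-05 to 0.0709, 0.00195 to 0.0709 and 0.00195 to 0.0798. Low depth limits TM4SF4 and ARSE most among the named genes, with means of 16 and 38 recovered reads in the knockdown.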

Other observations

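The lists in the next paragraph, and all tests of them, were chosen after the data were examined, as were the tests of a swap, of RNA from other cells and of the unfolded protein response below. Leaving out control library 1 was a setting fixed in advance, but its use as a test of the stress response list was chosen after the result was seen.

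Beyond the fixed lists, several genes of amino acid transport and of tRNA charging fell, and 3 tubulin genes and 1 metallothionein gene rose. Of 19 tested amino acid transporters 10 fell and 0 rose, among them the glycine transporter gene SLC6A9 (log2 fold change -1.89 ± 0.15), the glutamine transporter gene SLC1A5 (-1.73 ± 0.16) and the cationic amino acid transporter gene SLC7A1 (-1.68 ± 0.28). Of 20 cytosolic aminoacyl-tRNA synthetases 8 fell and 0 rose, including MARS (-1.56 ± 0.16), YARS (-1.41 ± 0.15) and CARS (-1.37 ± 0.13), while 0 of 16 mitochondrial synthetases passed. Of 13 tubulins 3 rose, TUBA4A, TUBB2A (1.44 ± 0.14) and TUBB4B (0.97 ± 0.19), and of 3 metallothioneins MT1X rose. MT2A, at 213 FPKM in control and 604 in knockdown, did not pass (adjusted p = 0.127). Tubulins and metallothioneins have close paralogs and pseudogenes, so reads may be split between them. Camera adjusted p over these 5 lists was 1.50e-09 for transporters, 1.53e-05 for cytosolic synthetases, 3.57e-05 for tubulins and 0.0236 for metallothioneins. With an estimated correlation the camera adjusted p was 0.139, 0.139, 0.197 and 0.297 in the same order. The lists were chosen after the data were examined, so these p-values are no independent test. Without control library 1, 11 transporters, 12 cytosolic and 1 mitochondrial synthetase and 1 tubulin fell, while 1, 4, 5 and 10 members of these lists and 3 metallothioneins rose. The transporter and cytosolic synthetase lists share members with the fixed stress response list.

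Of the 10 ways to split the 6 libraries into 3 and 3, only 1 gave as many genes as the real groups. That split was the real one, with 759 genes, and the highest other split gave 0 genes. The real split is always among them, so 10 splits are too few for a share under 0.05.

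Control library 1 differs from control libraries 2 and 3 by an SD of 0.748 on the log2 scale over 10714 protein-coding genes, against 0.186 between control libraries 2 and 3. A swap with a knockdown library would put INAVA in the knockdown range, but it measured 20.4 FPKM there, and no knockdown library lay in the control range. RNA from fibroblasts, leukocytes or endothelial cells is also argued against, since 0 of their markers reached 5 FPKM in control library 1 at over 3 times the highest other library. A trend on transcript length took up 48.2% of the variance of the difference, against 7.76% for GC content, which leaves a bias from RNA integrity or library preparation open as a possible explanation for part of it. After removal of that trend an SD of 0.539 remained, and no value in the tables decides how much of this comes from the culture itself.

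The fall of amino acid and stress response genes may reflect lower activity of the ATF4 branch of the stress response in the knockdown cells, a hypothesis formed on these data. The list median was -1.57 without control library 1 (quartiles -2.19 and -1.10) and -1.51 after removal of the length trend, when 19 of 23 members were lower past the test, so neither that library nor the length trend accounts for it. A fall of the whole unfolded protein response by as much is argued against, since the median of that list was -0.13 without control library 1 (quartiles -0.40 and 0.04). A smaller fall of it stays open, with 9 of 20 members lower and 0 higher there (camera adjusted p = 0.0186, adjusted p = 0.405 with an estimated correlation). Differences in medium, cell density or RNAi reagent between the groups stay open as untested, since the labels give none of them.

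The comparison of cytosolic with mitochondrial synthetases was chosen because cytosolic members had fallen in these data, so it tests neither a difference between the classes nor the hypothesis on ATF4. Among 17 cytosolic members outside the fixed list and 16 mitochondrial members, the median log2 fold change without control library 1 was -0.33 and 0.07, a difference of -0.40. With all 6 libraries the difference was -0.46. Of all 20 cytosolic members, the 3 on the fixed list included, 12 were lower and 4 higher without control library 1, FARSB among the latter (0.40 ± 0.06). Of the 16 mitochondrial members 5 were higher and 1 lower there.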
